A study of Oryza sativa Japonica Group with 20 samples.

How the data were processed

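The series measured RNA and the repressive histone mark H3K27me3 in rice seedlings (Oryza sativa, Japonica group). The labels name 20 samples. RNA sequencing covered 12 libraries in 4 groups of 3 replicates: wild type, the slr1 knockout of the DELLA protein SLR1, untreated control seedlings, and seedlings given 100 uM gibberellin (GA) through the roots for 1 h. H3K27me3 chromatin immunoprecipitation covered 6 libraries in 3 groups of 2 replicates: libraries labelled control, libraries labelled GA (100 uM for 6 h) and slr1 libraries. Input libraries (2 samples) had no file and were not analysed here. The slr1 and wild-type seedlings were 12 days old, per the series' design text. Groups came from the labels alone. No label says whether the replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

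The RNA files were tables of genes, 1 per experiment. Per the submitters' processing notes, the tools were HISAT2, featureCounts 2.0.0, DESeq and DESeq2 1.38.3, and the paired-end libraries were made with a TruSeq RNA kit, per the labels' protocols. The genome build and strand setting are not given in the sources used here. The value of each library was deposited as a signal: reads per gene divided by 1 size factor for the library. The deposited tables also hold the authors' mean level over libraries (signal), their log2 fold change and its error, their test statistic (a score) and their p-value with its adjusted form. The tables list 33838 genes for slr1 and 31290 for GA. They were normalized separately, so tests ran only within a table. In every library 100% of the values were whole multiples, within 0.01, of the smallest value above 0, so the reads were recovered. They came to between 27778578 and 28010807 per library in the slr1 experiment and between 17919838 and 20979965 in the GA experiment.

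Replicates were compared before they were averaged. Differences in reads per gene between 2 replicates, squared and divided by their counting variance, averaged between 17.6 and 89.2 in the slr1 experiment and between 1.88 and 3.04 in the GA experiment, where counting noise alone gives 1. Their medians in the GA experiment lay between 0.746 and 0.813, against 0.455 for counting noise. All libraries were kept as separate replicates. Replicates of the GA experiment thus differed by more than counting noise but far less than those of the slr1 experiment, so small changes can pass the test there.

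Genes with a value of at least 10 in at least 3 of the 6 libraries were tested. The filter was set after the values were seen and before any test. limma 3.58.1 (R 4.3.3) was run on log2(value + 1) with a trend, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes on this scale understate the change of low genes. SE is limma's standard error. Against a group in which every library was at 0, the fold was computed against 3 reads over the group, which covers counting error only. Since the deposited values are not counts, edgeR 4.0.16 (quasi-likelihood test, TMM) on the recovered reads was an added alternative, and DESeq2 was not rerun.

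Simulated counts held 200 changed genes with a mean level of at least 50, drawn 5 times from the means and libraries of each experiment. A gene counted as found at an adjusted p under 0.05, without the 2-fold minimum that a call needs. In the slr1 experiment (25226 genes tested on average) limma found 35.8% of 2-fold and 89.8% of 4-fold changes. Of the genes found there, 7.88% were false. It found 99.4% and 100% in the GA experiment (23253 genes tested), with 6.46% false. The threshold was 5%, so the false share was somewhat above it. Shares for called genes were not measured, and fewer 2-fold changes would reach the 2-fold minimum. In the data far more genes than 200 passed on p, 6248 in slr1 and 7681 after GA. The adjusted threshold then falls at another p, so the shares found and the false shares do not carry over to the data.

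The RNA tests, apart from their filter and the alternatives added later, the gene lists and the rule for naming genes were fixed before the data were examined. The H3K27me3 regions were chosen afterwards. The tables identify genes by locus IDs only, and the reference gene table matched 0 of the 34555 IDs. The names of the 38 genes in 5 lists are pairs of symbol and ID written from general knowledge with the lists, and were not checked against an annotation. These lists are GA biosynthesis, GA inactivation, GA perception and signalling, KNOX homeobox, and Polycomb with H3K27 demethylase. Lists defined by product descriptions (such as expansins, cyclins, histones, ribosomal proteins, leaf, root and handling-stress markers) had no IDs and were not tested. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's members move, on balance, one way or change in either direction, and compares them with no other genes. All were adjusted over the 5 lists. Named genes were SLR1, every called member of the GA lists with the tested GA20ox, GA3ox and GA2ox genes, up to 4 members of the other lists with the smallest adjusted p, and of the largest changes among called genes with a mean level of at least 50, the top 2 IDs each way. The fixed rule took 8 each way, and 2 were kept afterwards since these IDs carry no name. Regions were named by the rule fixed for genes, from the 5 lost and 5 gained with the largest covered length times fold enrichment. Near-identical neighbours of KO2 and FIE2 and overlapping or antisense genes can share reads, so counts for them are uncertain.

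The H3K27me3 files were lists of broad peaks, 1 per library. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, Bowtie2 2.4.4, deepTools 3.5.0 and MACS2 2.2.7.1. Each deposited peak has a score, a fold enrichment and a p and q given as -log10 values, all the authors' own. These describe a peak within its list. The smallest -log10 q was between 1.00 and 1.03, so lists held peaks with q up to about 0.1, and read depth per library is not given in the sources used here. Coordinates are those of the files, counted from 1, and their build is not given in the sources used here.

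The planned unit was the gene, but no gene coordinates for these IDs were supplied. Peaks of all 6 libraries were therefore joined into 15519 regions. A region was marked in a library when peaks covered at least 200 bp of it. It was lost when marked in both libraries labelled control and in neither of the other group, and gained in the reverse case. Regions and genes were not joined, so the planned tests between H3K27me3 and expression were not run. Peak sets were compared by the Jaccard index of covered bases (bases shared over bases covered in either), with an exact permutation test over the 15 ways to part 6 libraries into 3 pairs. Overlap of regions lost in both comparisons was set beside independent lists and beside 1000 shuffles of each region's marks among the 6 libraries, which do not keep the sizes of the real lists. The step that finds lost and gained regions recovered 100 of 100 planted lost and 100 of 100 planted gained regions, with 0 wrong. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

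Peak names inside the lists labelled control hold the text 6h, and those inside the lists labelled GA hold the text CK, which the RNA labels use for control. Those inside the slr1 lists hold the text j3, which does not name slr1. The GEO labels were kept. If the peak names are right, every direction between the libraries labelled control and GA turns round, and slr1 was compared with GA-treated seedlings. Alternatives changed the thresholds, filters, pseudocount, replicate block and each replicate, and chosen after seeing the data were edgeR on recovered reads, the authors' deposited results, TMM scaling, joined regions, windows of 1 kb, the strongest peaks of each library up to the same covered length of 20 Mb, exchanged labels of control and GA, and 1 control library for each H3K27me3 comparison.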

Results

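The data covered rice seedlings that lacked SLR1 or received GA. SLR1 is the DELLA protein of rice, a repressor of the response to the growth hormone GA that is degraded when GA is sensed. RNA was measured in 3 wild-type, 3 slr1, 3 control and 3 GA-treated (1 h) libraries. H3K27me3, a histone mark laid down by the Polycomb repressive complex, was measured in 2 libraries labelled control, 2 labelled GA (6 h) and 2 of slr1. Between 27778578 and 28010807 reads per library were assigned to genes in the slr1 experiment, and between 17919838 and 20979965 in the GA experiment. Levels are given as normalised reads, mean ± SD.

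The comparison of slr1 with wild type asked which genes change when the DELLA repressor is missing. Of the tested genes, 6 of 9 GA-inactivating genes and 3 of 5 KNOX homeobox genes rose, and 1 GA-inactivating gene fell. Of the Polycomb and H3K27 demethylase genes, 0 of 6 passed the test. SLR1 itself (LOC_Os03g49990) stood at 6133, 6810 and 7340 normalised reads in the wild-type libraries and at 7310, 6380 and 7444 in the slr1 libraries (log2 fold change 0.06, SE 0.13, limma adjusted p = 0.759). The kind of mutation is not given in the sources used here, so the transcript level did not check the knockout label.

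Of the 10 genes in the GA inactivation list, whose enzymes remove active GA or its precursors, 9 were tested, 6 rose, 1 fell and 2 did not pass. GA2ox3 (LOC_Os01g55240) rose from 768 ± 86.0 to 3973 ± 1026 (n = 3 each), a log2 fold change of 2.34 with SE 0.20 (limma adjusted p = 0.00131). GA2ox4 (LOC_Os05g43880) rose from 20.4 ± 3.97 to 176.0 ± 76.0, and GA2ox7 (LOC_Os01g11150) from 15.3 ± 8.47 to 102 ± 16.1. GA2ox1 (LOC_Os05g06670) rose 4.11-fold and EUI1 (LOC_Os05g40384), a cytochrome P450 that inactivates GA, rose 6.38-fold. GA2ox8 (LOC_Os05g48700) rose from 10.4 ± 6.58 to 89.2 ± 92.2 (limma adjusted p = 0.0457), a call that ended without wild-type replicate 1 or 3 or slr1 replicate 2 or 3 (highest adjusted p = 0.131). GA2ox9 (LOC_Os02g41954) fell from 164 ± 73.9 to 57.8 ± 3.10 (limma adjusted p = 0.0415), a call that ended without any 1 library except wild-type replicate 1 (highest adjusted p = 0.142). GA2ox5 and GA2ox6 had log2 fold changes of 2.35 and 2.30 and did not pass (limma adjusted p = 0.0644 and 0.0977). Adjusted over the list alone, 8 members rose and 1 fell. The list was higher as a set (camera adjusted p = 0.000386), a call that was lost at an adjusted p = 0.0737 with an estimated correlation. That estimate was -0.014, below the preset 0.01, so a higher correlation between members was not the reason.

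In the GA biosynthesis list, 2 of 8 tested members fell and none rose. CPS1 (LOC_Os02g17780), which acts at the start of the pathway, fell from 244 ± 9.33 to 73.2 ± 45.6 (log2 fold change -1.98, SE 0.52, limma adjusted p = 0.0324), a call that ended without any of the wild-type replicates (highest adjusted p = 0.0981). GA20ox1 (LOC_Os03g63970), a GA20 oxidase of the late pathway, fell from 419 ± 61.1 to 208 ± 25.2 (limma adjusted p = 0.00749), at the 2-fold threshold, and came to less than 2-fold without wild-type replicate 1 or slr1 replicate 1. GA20ox4 (LOC_Os05g34854) had a log2 fold change of -1.50 (limma adjusted p = 0.0822), SD1 (GA20ox2, LOC_Os01g66100), the semi-dwarf gene, 0.73 (adjusted p = 0.171) and D18 (GA3ox2, LOC_Os01g08220) -0.63 (adjusted p = 0.533), and these did not pass. For GA20ox4 the authors' deposited adjusted p was 0.0392, and edgeR's adjusted p was 0.116. Adjusted over the list alone, 0 rose and 2 fell. The list as a set did not pass (camera adjusted p = 0.412). In the GA perception and signalling list, 1 of 5 tested members was called: SLRL1 (LOC_Os01g45860), a SLR1-like gene, rose from 106 ± 22.5 to 255 ± 35.1 (limma adjusted p = 0.00739). GID1 (LOC_Os05g33730), the GA receptor, was lower by less than the 2-fold minimum, at 2234 ± 237 and 1347 ± 255 (limma adjusted p = 0.0161). That list as a set did not pass (camera adjusted p = 0.507), and adjusted over the list alone 1 member rose and 0 fell by at least 2-fold.

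KNOX homeobox genes, which act in the shoot meristem, were tested in full, and 3 of 5 rose. OSH15 (LOC_Os07g03770) rose from 56.7 ± 35.6 to 489 ± 139 (log2 fold change 3.30, SE 0.54, limma adjusted p = 0.00713). OSH43 (LOC_Os03g56110) rose from 5.36 ± 2.07 to 91.8 ± 33.8, and OSH71 (LOC_Os05g03884) from 70.9 ± 48.0 to 264 ± 43.2, a call that ended without wild-type replicate 3 or any 1 slr1 replicate (highest limma adjusted p = 0.0766). OSH1 (LOC_Os03g51690) stood at 112 ± 73.2 and 463 ± 206 and did not pass (limma adjusted p = 0.0502), though it passed without wild-type replicate 1 or slr1 replicate 3. It did not pass with edgeR (adjusted p = 0.0503), while the authors' deposited adjusted p was 0.00194. Wild-type replicate 2 held the lowest wild-type value for 4 of the 5 members: 30.9 normalised reads beside 173 and 131 for OSH1, 19.2 beside 90.0 and 61.0 for OSH15, 21.3 beside 117 and 74.2 for OSH71, and 19.2 beside 98.8 and 37.6 for OSH6. Adjusted over the list alone, 4 members rose. The list was higher as a set (camera adjusted p = 0.00415), and the call was lost at an adjusted p = 0.450 with an estimated correlation, and at 0.0786 and 0.0571 without slr1 replicate 1 or 2. Of the Polycomb and H3K27 demethylase list, 0 of 6 tested members were called by limma or edgeR (1 had an unadjusted limma p under 0.05), 0 also when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.824). CLF (LOC_Os06g16390), a histone methyltransferase, had a log2 fold change of -0.28 (limma adjusted p = 0.121) and EZ1 (LOC_Os03g19480) of 0.18 (adjusted p = 0.368).

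Among 25132 genes tested, 1651 rose and 1795 fell in slr1, which is 13.7% of them. Several of the largest changes ran between strong expression and none. LOC_Os08g15230 was at 0 in all 3 wild-type libraries and at 2082 ± 178 in slr1 (n = 3), at least 2048-fold higher. LOC_Os04g08828 was likewise at 0 in wild type and reached 240 ± 142 in slr1, at least 236-fold higher. LOC_Os11g09979 fell from 2383 ± 381 to 0.326 ± 0.565, and LOC_Os01g41240 from 4895 ± 925 to 2.98 ± 2.61. The count of genes that fell was 993 without wild-type replicate 3.

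The comparison of GA-treated with control seedlings asked which genes respond within 1 h of GA. KNOX homeobox genes and 3 GA 2-oxidase genes rose, while a GA 20-oxidase and the GA receptor were lower by less than the 2-fold minimum. Every tested KNOX member, 4 of 4, rose. The replicates may be technical, since no label says otherwise, so the p-values may not cover the spread between plants. OSH1 rose from 7.97 ± 2.08 to 64.9 ± 8.93 normalised reads (n = 3 each; log2 fold change 2.89, SE 0.29, limma adjusted p = 1.06e-09), and OSH15 from 7.66 ± 1.27 to 62.6 ± 5.45. OSH6 (LOC_Os01g19694) rose from 2.90 ± 0.947 to 18.4 ± 4.30 and OSH71 from 11.8 ± 2.86 to 47.6 ± 11.9. OSH43 was below the level tested. Adjusted over the list alone, all 4 rose as well. The list was higher as a set (camera adjusted p = 0.000148), and the call was lost at an adjusted p = 0.159 with an estimated correlation.

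In the GA inactivation list, 3 of 9 tested members rose and none fell by at least 2-fold. GA2ox3 rose from 186 ± 13.6 to 503 ± 44.8 (log2 fold change 1.43, SE 0.09, limma adjusted p = 1.18e-14). GA2ox1 rose from 6.11 ± 1.40 to 23.0 ± 2.75 and GA2ox7 from 11.9 ± 1.04 to 34.3 ± 4.11. GA2ox9 passed on p alone and was lower, at 951 ± 46.6 and 528 ± 9.76 (log2 fold change -0.85, limma adjusted p = 1.06e-13). GA2ox8 passed on p alone at a log2 fold change of 0.44. GA2ox4, GA2ox5, GA2ox6 and EUI1 had log2 fold changes of -0.36, -0.15, 0.45 and -0.20 and did not pass. Adjusted over the list alone, 3 rose and 0 fell by at least 2-fold. Against other genes the list did not pass (camera adjusted p = 0.223), while its members moved up on balance (fry adjusted p = 0.00185).

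In the GA biosynthesis list, 0 of 8 tested members were called by limma or edgeR (6 had an unadjusted limma p under 0.05), while 1 was higher and 4 were lower on p alone, and 1 higher and 5 lower adjusted over the list alone. GA20ox1 stood at 575 ± 8.19 in control and 334 ± 15.2 after GA (n = 3 each; log2 fold change -0.78, SE 0.07, limma adjusted p = 4.81e-11). SD1 was at -0.32, GA20ox4 at -0.21 and KO2 (LOC_Os06g37364) at -0.28 on the log2 scale, and KAO (LOC_Os06g02019) at 0.46. D18 was at 0.17 (limma adjusted p = 0.489). GID1 stood at 1917 ± 114 in control and 1181 ± 20.3 after GA (log2 fold change -0.70, limma adjusted p = 4.46e-14). SLR1 was at 0.34 (limma adjusted p = 1.09e-10) and SLRL1 at 0.76 on the log2 scale. Against other genes neither list passed (camera adjusted p = 0.154 for biosynthesis and 0.313 for perception and signalling), while the members of the biosynthesis list moved down on balance (fry adjusted p = 0.00691) and those of the perception and signalling list did not pass (fry adjusted p = 0.212). No member of the perception and signalling list was called by limma or edgeR, 0 of 5, over all genes or adjusted over the list alone, while 4 had an unadjusted limma p under 0.05. EZ1 was at -0.19 (limma adjusted p = 0.0106) and CLF at 0.15 (adjusted p = 0.0229). Of the Polycomb and H3K27 demethylase list, 0 of 6 members were called by limma or edgeR (3 had an unadjusted limma p under 0.05). Adjusted over the list alone 0 were called, and the set did not pass (camera adjusted p = 0.879). Its median log2 fold change was 0.00 and its mean -0.01, with camera's direction down. In its test of movement on balance, fry passed the GA inactivation and KNOX lists in slr1 (adjusted p = 0.000381 and 0.0204) and the KNOX list after GA (0.000268), and not the other lists in slr1 (lowest 0.122) or Polycomb after GA (0.741). In its test of change in either direction, fry passed 4 of the 5 lists in slr1, all but Polycomb (adjusted p = 0.117), and all 5 after GA (highest 0.000403).

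**Figure D1:**
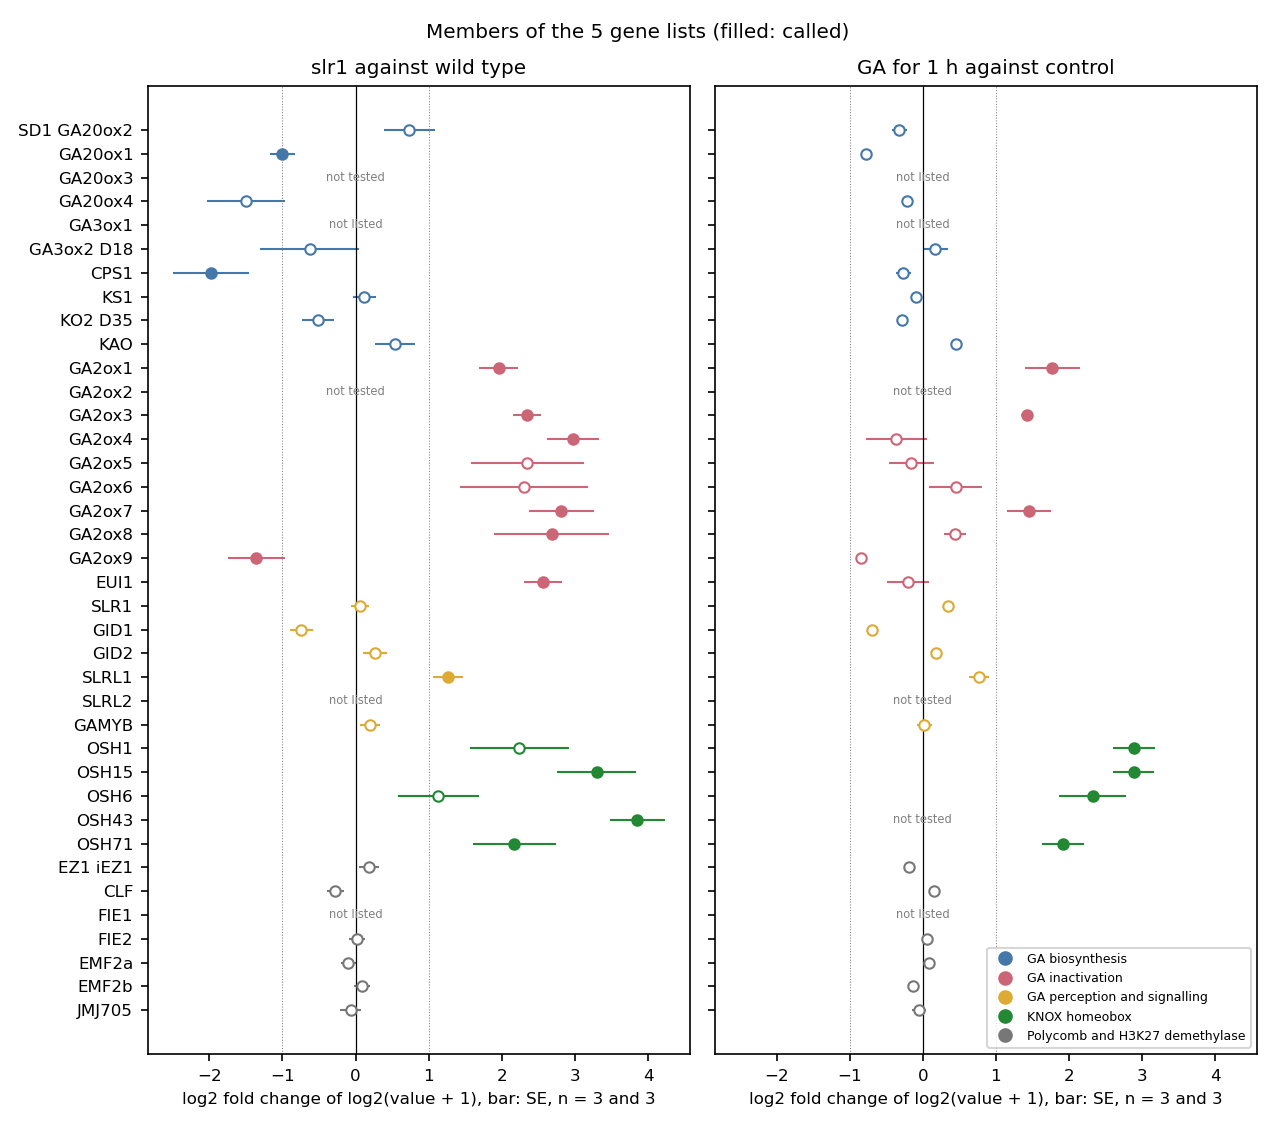
Log2 fold change (horizontal axis, log2 scale, with limma's SE) of each member of the 5 gene lists (vertical axis) in slr1 against wild type and after GA for 1 h against control, n = 3 per group. Filled points were called: 6 GA inactivation genes rose in slr1 and 3 after GA, while 3 of 5 and 4 of 4 tested KNOX genes rose.

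Among 23283 genes tested, 284 rose and 232 fell after GA, which is 2.22% of them. Without the 2-fold minimum, 3981 were higher and 3700 lower. LOC_Os10g26340 rose from 16.5 ± 13.1 to 104 ± 3.30 (log2 fold change 3.04, and 2.15 to 3.64 without 1 library). LOC_Os05g29810 rose from 54.3 ± 8.53 to 298 ± 34.7 (n = 3 each). LOC_Os11g26790 fell from 405 ± 12.1 to 14.1 ± 3.25 and LOC_Os05g46480 from 170 ± 18.4 to 4.44 ± 0.363.

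Comparison of both gene sets asked whether loss of SLR1 and a short GA treatment change the same genes. Of 22958 genes tested in both, 55 rose in both, where independent lists of these sizes give 16.7 (2-sided Fisher exact test across genes, odds ratio 3.98, 95% interval 2.89 to 5.41, adjusted p = 1.41e-14 over 4 pairs of directions). Without the 2-fold minimum the excess did not pass, at 513 genes against 481 (adjusted p = 0.0921), while 620 genes were up in slr1 and down after GA, against 442 (adjusted p = 4.84e-21), 695 were down in both, against 464 (adjusted p = 4.04e-32), and 322 were down in slr1 and up after GA, fewer than the 505 for independent lists (adjusted p = 1.97e-23). These 55 were 20.3% of the genes that rose after GA, beside 6.18% of all genes. GA2ox1, GA2ox3, GA2ox7, OSH15 and OSH71 rose in both. The 19 genes that fell in both, against 12.7 for independent lists, did not pass (adjusted p = 0.144). Neither did the 16 genes up in slr1 and down after GA (11.9 for independent lists, adjusted p = 0.225) or the 11 genes down in slr1 and up after GA (17.9, adjusted p = 0.144). Those counts depended on the setting. Genes up in slr1 and down after GA passed without wild-type replicate 3 (18 against 8.41), slr1 replicate 1 (19 against 10.4), GA replicate 2 (24 against 11.8) or GA replicate 3 (21 against 12.1). Genes down in both passed with edgeR (26 against 12.6 for independent lists, adjusted p = 0.00117) and without wild-type replicate 2 (31 against 11.5), control replicate 1 (17 against 9.95) or GA replicate 3 (21 against 13.0). Genes down in slr1 and up after GA were fewer than for independent lists, and passed, without any 1 of 7 libraries, as without wild-type replicate 3 (2 against 11.1). LOC_Os11g26790, which fell after GA, rose in slr1 from 24.1 ± 30.2 to 406 ± 254 (limma adjusted p = 0.0101). Across all 22958 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.03 and a Spearman rho of -0.02. Of the 101 genes called in both, 74 moved in the same direction. Both tables were normalized separately and have their own control libraries, and the difference between the comparisons was not tested.

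**Figure D2:**
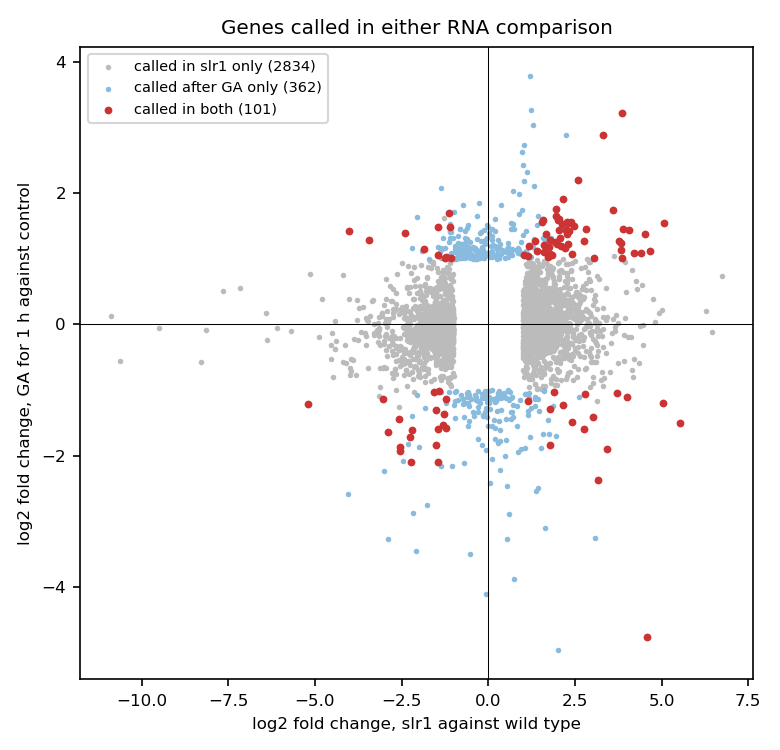
Log2 fold change in slr1 against wild type (horizontal axis) and after GA for 1 h against control (vertical axis) of genes called in either, 1 point per gene. The 101 genes called in both are red, and 55 of them rose in both.

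H3K27me3 peaks covered between 21.3 and 27.8 Mb per library. The libraries labelled control had 13520.5 ± 132 peaks over 26.1 ± 1.45 Mb (SD, n = 2), those labelled GA 13388.5 ± 356 peaks over 23.3 ± 1.17 Mb, and the slr1 libraries 12648.5 ± 1343 peaks over 24.6 ± 4.53 Mb. The slr1 replicates differed most, at 27.8 and 21.3 Mb. The authors' mean fold enrichment per peak was 3.65 ± 0.0394 in the libraries labelled control, 3.42 ± 0.211 in those labelled GA and 3.19 ± 0.143 in slr1. Of 15519 joined regions, 9076 (58.5%) were marked in all 6 libraries.

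Peak sets of the same group were not more alike in every group. The Jaccard index averaged 0.777 within and 0.747 between groups, and no other of the 15 ways to pair the libraries gave as large a gap (exact permutation test, 1-sided, p = 0.0667, the smallest this design allows). The libraries labelled control had an index of 0.825 with each other, those labelled GA 0.787 and the slr1 libraries 0.718. Libraries labelled control and GA averaged 0.783, libraries labelled control and slr1 0.739, above the slr1 pair, and libraries labelled GA and slr1 0.718. The gap was 0.0301. The SD of 0.0543 between the 3 same-group values shows how the groups differ and is not the error of the gap. Leaving out a library also removes its group's only same-group value. The gap was then 0.0157 and 0.0106 without control replicate 1 or 2 and 0.0502 and 0.0507 without slr1 replicate 1 or 2.

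**Figure D3:**
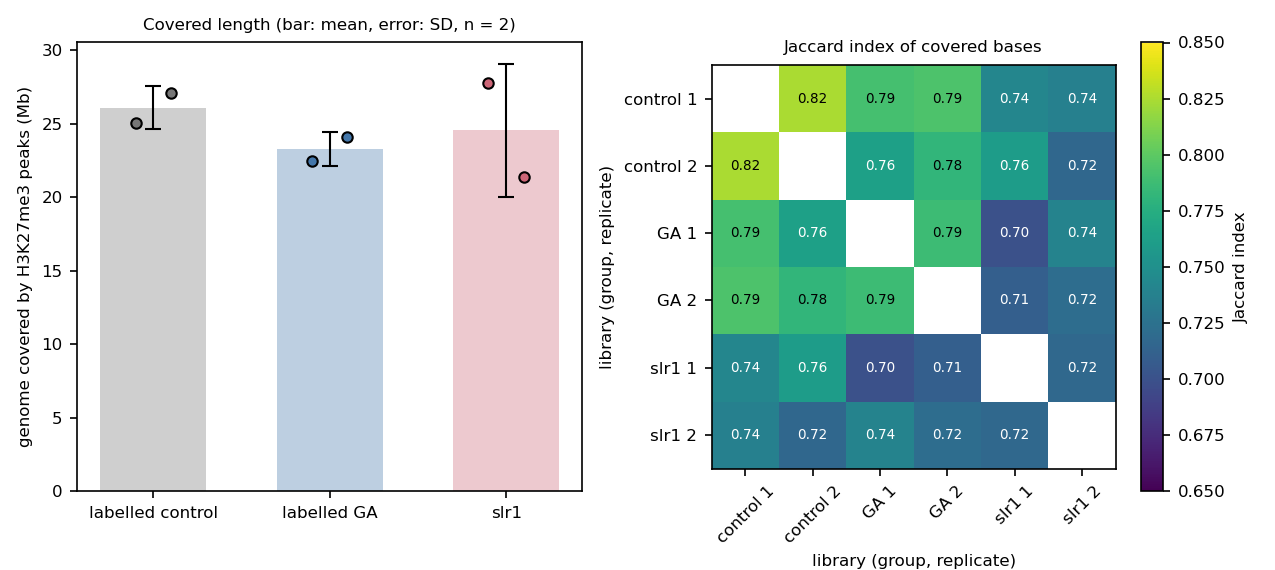
Left, genome length covered by H3K27me3 peaks (Mb) per library (points) with the group mean (bar) and SD (error, n = 2). Right, the Jaccard index of covered bases for each pair of libraries, highest between the libraries labelled control at 0.825.

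The comparison of H3K27me3 in slr1 with the libraries labelled control asked where the mark differs without SLR1. No H3K27me3 library came from the wild type of the slr1 RNA experiment, so slr1 was set against libraries of the GA experiment. The age of those seedlings is not given in the sources used here. Genotype therefore cannot be told apart from experiment or age. Of the 5 lost regions with the largest covered length times fold enrichment, 4 lay on chromosome 11. These carried the mark in all 4 libraries labelled control or GA and in neither slr1 library. Regions parting slr1 from those 4 libraries were densest on that chromosome, between 5000001 and 6000000. A difference in DNA of the slr1 line there cannot be told apart from a loss of the mark. At chromosome 11, 5944378 to 5949159, peaks covered 4304 ± 572 bp in the libraries labelled control (n = 2) and 0 bp in slr1. At chromosome 11, 5998125 to 6003727, they covered 5185 ± 591 bp and 0 bp, and at chromosome 4, 33678941 to 33684507, 2992 ± 1455 bp and 0 bp. On chromosome 12, at 19296498 to 19306726, the mark was present in slr1 alone, over 7668 ± 2525 bp, and on chromosome 7, at 6580322 to 6585238, over 3998 ± 1300 bp with 688 bp in 1 library labelled GA. Genes at these positions were not identified here.

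In all, 844 regions were lost in slr1, 7.28% of the 11595 marked in both libraries labelled control, and 197 were gained. Against the libraries labelled GA, which would be the controls if the peak names are right, 550 were lost and 306 gained. The other splits of the same 4 libraries gave 175 and 397 changed regions, against 1041 for the real one, and with 3 splits no p below 1/3 is possible. The counts depended on the library left in the slr1 group, when 1 library stands for it: without slr1 replicate 2, the library with less coverage, 975 were lost and 1453 gained, and without slr1 replicate 1, 2025 were lost and 312 gained. Lost regions were narrow, with a median of 594.5 bp, and 7 spanned at least 3000 bp.

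**Figure D4:**
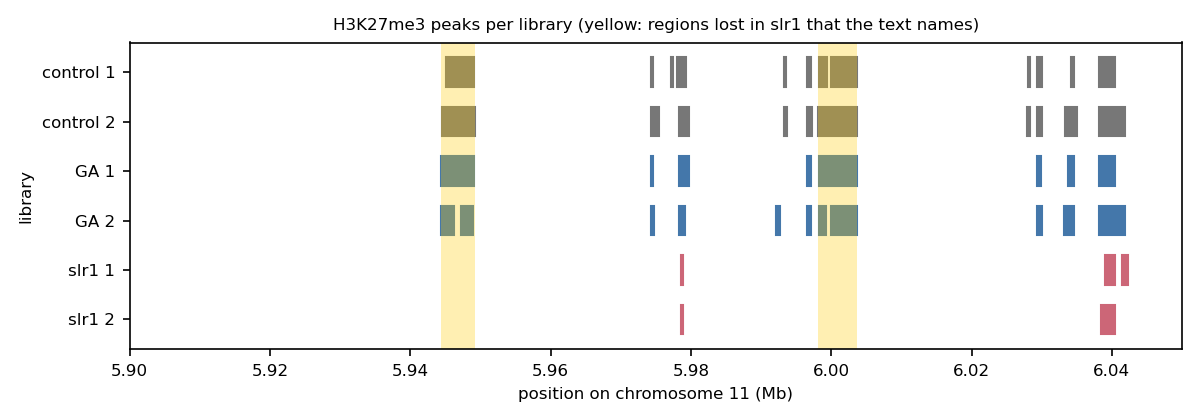
H3K27me3 peaks of each library (rows) along chromosome 11 (horizontal axis, Mb). The yellow regions, 5944378 to 5949159 and 5998125 to 6003727, had peaks in the 4 libraries labelled control or GA and none in the slr1 libraries. A difference in DNA of the slr1 line there cannot be told apart from a loss of the mark.

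The comparison of the libraries labelled GA and control asked how H3K27me3 changes within 6 h of GA. The changed regions were small. At chromosome 7, 1950017 to 1952426, peaks covered 2193 ± 308 bp in the libraries labelled control (n = 2) and 0 bp in those labelled GA. At chromosome 1, 41745571 to 41748708, they covered 1610 ± 187 bp and 0 bp. On chromosome 4, at 31915824 to 31917055, 1086 ± 111 bp were covered in the libraries labelled GA and 0 bp in those labelled control, and on chromosome 2, at 28796292 to 28797515, 954 ± 383 bp and 0 bp. In all, 450 regions were lost and 94 gained, where the other splits of the 4 libraries gave 293 and 226 changed regions against 544 for the real one. Without 1 of these libraries, whichever it was, the lost regions numbered between 712 and 1138 and the gained between 189 and 588. The peak names inside these 4 lists hold 6h where the label is control and CK where it is GA. If those names are right, the direction turns.

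Of the regions lost in slr1, 193 were also lost in the libraries labelled GA. Independent lists give 32.8 among the 11595 regions marked in both libraries labelled control. Both comparisons share those control libraries, so part of the excess may come from them, and giving each comparison its own control library leaves the same 193, since a region lost in both must be marked in both. Shuffling each region's marks among the 6 libraries gave 222 lost and 222 gained regions per comparison on average, with 75.8 and 63.6 shared. Those lists do not have the real sizes (844 and 450 lost, 197 and 94 gained), so the shuffles did not show how much the shared libraries give. Gained regions overlapped in 13, against 8.66 for independent lists. If the peak names are right, the 193 were marked after GA and neither in control nor in slr1.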

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

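Tests chosen only after the result was seen were those at equal covered length, the one on the names in the peak lists, and the reading of the counts without 1 slr1 library, with the rule on its coverage that left that reading open. For CLF, a Polycomb methyltransferase, every slr1 library lay below every wild-type library (log2 fold change -0.28, not past the threshold at a limma adjusted p = 0.121) and every GA library above every control library (0.15, limma adjusted p = 0.0229, under 2-fold). The difference was not tested. Such separation of 3 against 3 libraries occurs by chance in 10% of genes, and 45.1% of tested genes showed it in slr1 and 43.3% after GA.

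More H3K27me3 regions were lost (450) than gained (94) in the libraries labelled GA, whose covered length and fold enrichment were lower. Limited to the strongest peaks of each library up to 20 Mb, the ratio of lost to gained regions went from 4.79 to 0.0259, but the limit kept between 8082 and 8793 regions in the libraries labelled GA and between 6574 and 7433 in those labelled control, which by itself pulls the ratio down. Lower enrichment or depth therefore cannot be told apart from a loss of the mark after GA, the biological explanation. In 4 of 4 lists the peak names differ from the label, which is what exchanged labels predict. Names in the lists labelled GA hold CK, used for control. Names in those labelled control hold 6h, a time given for GA, but do not name GA. The GEO labels say the reverse, and no measured value in the lists shows which is right. Exchanged labels therefore cannot be told apart from correct ones either.

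More regions were lost (844) than gained (197) in slr1. The ratio went from 4.28 to 0.671 without slr1 replicate 2, the library with the least coverage, and to 6.49 without slr1 replicate 1, but each leaves a group of 1 library, and replicate 1 alone covered more than any control library (27.8 Mb). At equal covered length the ratio was 0.762, but the limit kept 5906 regions in slr1 replicate 1 and 8658 in replicate 2. Lower enrichment or depth of replicate 2 or of both slr1 libraries therefore cannot be told apart from a loss of the mark in slr1. Nor can a difference between the experiments, since slr1 had no H3K27me3 control of its own. The 4 top lost regions on chromosome 11 had no peak in either slr1 library, but the definition of a lost region requires this. It therefore does not tell these explanations apart.

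In the RNA comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split called 3446 genes in slr1 and 516 after GA, and the highest other split called 0 in each, with 1 of the 10 splits (the real one) as large. Every other split mixes both groups, so a group difference widens the spread within its sides. The 0 therefore does not show what unchanged libraries would give.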

How the results depend on the processing

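Alternatives chosen after seeing the data were edgeR, the authors' table, TMM scaling, windows of 1 kb, peaks at equal covered length, exchanged labels and 1 control library for each H3K27me3 comparison. Of 73 results for named genes over these and the other settings, 49 kept their side of the threshold in each and 0 called ones changed direction. Over all 1137 values, 26 no longer passed, all in slr1, and 25 newly passed, 12 in slr1 and 13 after GA, the latter all without the fold minimum. CPS1, GA20ox1, GA2ox8, GA2ox9 and OSH71 in slr1 lost their call in 4 to 6 of 16 alternatives each, and 18 of these 26 losses came without 1 library, where fewer samples were tested. Genes up and down in slr1 numbered 3026 and 3222 without a fold minimum and 953 and 895 at an adjusted p under 0.01. Without 1 library the count of genes down ranged from 993 to 1777. Genes up and down after GA numbered 3981 and 3700 without a fold minimum, up were 180 with a pseudocount of 5, and down were 392 with no filter. edgeR called 1755 up and 1823 down in slr1 and 299 and 236 after GA, and the authors' deposited table holds 2014 and 2155, and 245 and 207. TMM scaling moved the median of all genes by less than 0.1. The replicate numbers do not pair the libraries: same-numbered libraries correlated at 0.09, 0.19 and -0.16 in slr1 and at -0.01, -0.03 and -0.02 after GA, and only replicates 1 and 2 of slr1 correlated best with their own number. With the replicate block, 1529 rose and 1608 fell in slr1, and 279 and 227 after GA.

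With an estimated correlation, the adjusted p was 0.0737 for GA inactivation and 0.450 for KNOX in slr1, and 0.159 for KNOX after GA, each the highest over its alternatives. Without 1 library, at the preset correlation, it ranged from 0.000344 to 0.0786 for KNOX in slr1, over the threshold without slr1 replicate 1 or 2. Genes up in both, up then down, down then up and down in both (slr1 named before GA) numbered 513, 620, 322 and 695 without a fold minimum (481, 442, 505 and 464 for independent lists), where the first no longer passed (adjusted p = 0.0921) and the others did, and 30, 10, 2 and 9 at an adjusted p under 0.01. Without 1 library, up then down was 12 to 24 and passed in 4 cases, down then up 2 to 20 and passed in 7, and down in both 10 to 31 and passed in 3. With edgeR, down then up was 17, and down in both was 26 and passed. With the replicate block, genes up then down (18), down then up (8) and down in both (23) passed. The cause was not tested.

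Peaks with q under 1e-5 covered 20.6, 17.0 and 16.7 Mb in the control, GA and slr1 libraries. At that q, 1460 regions were lost and 14 gained in slr1, and 20 gained in the libraries labelled GA. Without 1 library, 975 to 2025 were lost and 250 to 1453 gained in slr1, and 712 to 1138 lost and 189 to 588 gained in the libraries labelled GA, since 1 library then decides a group. With windows of 1 kb, 1803 were lost and 645 gained in slr1, and 1429 and 234 in the libraries labelled GA. With at least 50% of a region covered, 763 were lost in the libraries labelled GA. At equal covered length 157 were lost and 206 gained in slr1. In the libraries labelled GA 16 were lost and 617 gained, where the limit itself kept fewer regions in the control libraries. With exchanged labels, 550 were lost and 306 gained in slr1, 94 lost and 450 gained after GA, and 52 lost and 82 gained in both. With 1 control library for each comparison the regions lost and gained in both stayed 193 and 13, as the definition requires. Joining peaks under 500 bp apart and a 1 bp overlap moved nothing. Gene spans with 1 kb upstream and tests of the mark on genes were not run, for want of gene coordinates, and DESeq2 and its size factors, meant for deposited counts, were not run on recovered reads.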

Other observations

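Tests chosen only after the result was seen were those on genes on in one genotype and off in the other, with their thresholds and windows, on the clustering of genes and of regions, and on the response of the window's genes to GA. In slr1, 18 genes were on only in wild type and 17 only in slr1 (at least 20 normalised reads in every library of one genotype and at most 3 in every library of the other). The GA comparison had 1 such gene. LOC_Os11g09979, which fell in slr1, stood at 1934 ± 97.0 in the untreated and 2110 ± 90.7 in the GA-treated seedlings (n = 3), and LOC_Os01g41240 at 5378 ± 178 and 3645 ± 82.6.

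Of these 35 genes, 4 lay within 50 consecutive tested genes on chromosome 11, as the locus IDs number them (from 10800 to 11940), with 3 on in wild type and 1 on in slr1 (permutation p = 0.00140 over 10000 shuffles, of which the densest also held 4). Regions that parted both slr1 libraries from all 4 H3K27me3 libraries labelled control or GA (405 lost and 140 gained) were also densest on chromosome 11. They were 11 of the 39 regions between 5000001 and 6000000 (permutation p = 0.0010, with 12 in the densest of 10000 shuffles). The shuffles took neighbouring regions as independent, so this p may be too small. Gene IDs and coordinates were not joined. A candidate explanation is that the slr1 line differs in DNA from wild type in these stretches of chromosome 11, which were not shown to be the same. Of the other genes in the gene window 19.6% were called in slr1, against 13.6% in the rest (Fisher exact p = 0.277), which leaves it open. A direct response to loss of SLR1 may also account for it: 0 of the 3 window genes tested after GA were called in the same direction, but 1 h may be too short, so the explanations cannot be told apart.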
